A study of Caenorhabditis elegans with 59 samples.

How the data were processed

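Small RNA and mRNA of whole gravid adults were read from 6 tables of deposited values covering 59 libraries, with no column of any sample left unused. Per the labels' protocols, animals were grown at 20 °C on E. coli OP50, RNA was isolated with Trizol, mRNA libraries were made from rRNA-depleted RNA over 200 nt, and small RNA of 16 to 30 nt was size-selected on gels and treated with polyphosphatase. The labels name a pair of stranded mRNA kits without saying which library used which, so a kit batch cannot be ruled out or removed, and counting by strand is not stated. Aligner, counting tool and genome release are not given in the sources used here.

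The deposited values have the unit signal: the authors divided read counts per gene by normalization factors, as the values themselves show. For small RNA, 100% of the values came out as whole reads within 0.01 after dividing by 1 step per library, so the deposited signal there was turned back into read counts. For mRNA, 94.76% to 97.44% came out whole within 0.1, the cause of the rest was not tested, and depth is given as approximate. Normalized totals of generation 1 small RNA were 1074258 ± 7803 in the wild type, 1617370 ± 57594 in prg-1, 485034 ± 9835 (n = 2) in mut-14 smut-1 and 497413 ± 4659 in the triple mutant. In generation 1 small RNA, the spread between replicates was as low as 1.10 times counting error (chi-square per degree of freedom). Floors of 3 reads in all-zero groups cover counting error only.

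The design assumed raw counts. The files held normalized values, so limma replaced edgeR as the main test and the design was otherwise kept as written. Gene names were taken from the tables and matched to a reference of assembly WBcel235 used for names and neighbours alone: 21281 of 22099 gene IDs matched in the polyA and generation 1 mRNA tables, 21555 of 23176 at generation 50, and 20028 of 20475, 12224 of 12423 and 7179 of 7479 in the small RNA tables. The mRNA tables also held 587 transposon entries and 158 second entries of a gene, which were dropped. The generation 50 small RNA table held 15366 piRNAs, 375 miRNAs and 191 transposons, and 41 genes listed in 2 classes, of which 13 with differing values were left out of tests across tables.

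Values were taken as log2(value + 1). Genes were tested where at least as many libraries as the smallest group reached 10, which left 14570, 14618 and 16328 genes in the mRNA tables and 7418, 7273 and 10968 features in the small RNA tables of generation 1, tm872 and generation 50. limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group over all groups of a table and a mean-variance trend, and Benjamini-Hochberg adjusted p under 0.05 was called. There were 18 contrasts, 3 differences between prg-1 effects of separate tables and 4 differences of the prg-1 effect between the mut-14 smut-1 and wild-type backgrounds. In n = 2 or 3 groups, leaving out a library can leave 1 sample, which is then assumed to vary like the other groups. Shares of small RNA classes were compared with a two-sided exact permutation test, which 3 against 3 libraries limits to 0.1. Overlaps of small RNA and mRNA calls used Fisher's exact test.

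Gene lists were fixed before the data were examined, as were the contrasts, the first set of alternatives and the rule for naming genes. The 27 lists were core histones, histone variants and linker histones, Argonautes, small RNA amplification and mutator factors, piRNA biogenesis factors, germ granule components, nuclear RNAi and heterochromatin factors, major sperm proteins, spermatogenesis, oocyte and eggshell, germline proliferation and meiosis, early embryo zygotic genes, vitellogenins, body wall muscle, cuticle collagens, male-specific neurons and seminal fluid, ribosomal proteins, ribosomal RNA genes, heat shock, intracellular pathogen response (pals genes), C-type lectins with lysozymes and antimicrobial peptides, F-box and MATH domain genes, transposons, ERGO-1 class targets, the silencing readouts bath-45, fbxb-97 and xol-1, neuropeptides and neuronal synapse, and intestine. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Named genes were the mutated genes, the 8 largest increases and 8 largest decreases among called genes at 10 CPM (counts scaled to library size) or more without overlap between groups (small RNA genes without piRNAs, miRNAs and structural RNAs, with 3 miRNAs each way), the 3 higher and 3 lower of each list by smallest p, the 8 genes with the largest opposite changes of small RNA and mRNA, and 5 each way for differences. A selection of these is printed, and xol-1 is printed where it was not called.

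Alternatives were median-ratio scaling (RLE), library totals, scaling to miRNAs at generation 50 (the other tables hold none), no filter, a stricter filter of 10 CPM, a replicate block, only the 2 groups compared, core histones summed, DESeq2 1.42.0 on recovered reads, and leaving out each library. Chosen after seeing the data were edgeR 4.0.16 on recovered reads, TMM scaling, pseudocounts of 0.5 and 5, generation 50 small RNA without piRNAs and miRNAs, and generation 50 mRNA without 2 doubted lines. The scripts were tested on simulated data with 200 changed genes. With 100 genes changed 2-fold and 100 changed 4-fold, limma recovered 71% and 91% in generation 1 mRNA of prg-1 (14618 genes), 35% and 59% at generation 50 (16328), 48% and 77% in generation 1 small RNA (7418), 21% and 88% at generation 50 (10968) and 70% and 97% for tm872 (7273), with at most 19 false calls in any of the 25 tests.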

Results

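The libraries came from whole gravid adult Caenorhabditis elegans. The strains were the N2 wild type, prg-1(n4357) and prg-1(tm872), which lack function of the PIWI Argonaute that binds piRNAs, mut-14(mg464) smut-1(tm1301), which lacks a pair of RNA helicases of the mutator complex that amplifies secondary small RNAs, and the triple mutant prg-1(n4357); mut-14 smut-1. Generation 1 mRNA had 12 libraries, 3 in each of the wild type, prg-1, mut-14 smut-1 and triple mutant, with about 12100000 to 23500000 reads each. Generation 50 mRNA had 3 independently kept lines of each of these 4 genotypes, with about 14300000 to 63800000 reads. Generation 1 small RNA had 11 libraries, 3 per genotype but 2 of mut-14 smut-1. Depth followed genotype: 224056 to 760735 counted reads in both mutator mutants, 1300861 to 2117438 in the others. Generation 50 small RNA had 12 libraries with 4417660 to 13038182 reads, which also listed piRNAs, miRNAs, transposons and the authors' target classes. A separate small RNA series compared 3 prg-1(tm872) with 3 wild-type libraries of animals 68 h old, with 1533620 to 2452755 reads. Another 6 wild-type mRNA libraries compared polyA-selected with total RNA at about 21000000 to 52000000 reads. Values are the deposited normalized counts, given as mean ± SD with n = 3 unless stated. Changes in log2 are given ± SE on the scale of log2(normalized count + 1), which understates the change of low genes. For each gene list, counts of higher and lower genes are followed in parentheses by the counts adjusted over the list alone, then by the median log2 change and the adjusted p of camera with a preset correlation between genes. Where that passed, a second adjusted p follows, with a correlation estimated from the data, which is the stricter test. Between libraries of 1 group, the correlation across genes ran from 0.919 to 0.982 in generation 50 mRNA and from 0.938 to 0.995 in the other 5 tables. Nothing says that replicates of the generation 1 and tm872 series came from separate cultures, so their p-values measure only the spread between these samples.

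The mutated genes were read first, since they check the labels. In generation 1 mRNA, mut-14 stood at 1810 ± 52.99 in the wild type, 1447 ± 40.4 in prg-1, 42.7 ± 5.82 in mut-14 smut-1 and 39.2 ± 7.30 in the triple mutant. The smut-1 mRNA was 1702 ± 33.4, 1331 ± 23.8, 251.4 ± 15.35 and 250.0 ± 27.6 in the same order. The prg-1 mRNA was 10339 ± 315 in the wild type and 7635 ± 303 in mut-14 smut-1, and 3905 ± 81.4 and 2708 ± 107 in the strains carrying prg-1(n4357). At generation 50, mut-14 was 2069 ± 32.8, 2030 ± 245, 84.6 ± 19.3 and 89.3 ± 11.4, and prg-1 was 10192 ± 514, 3815 ± 409, 10362 ± 737 and 3570 ± 200. The mut-14 smut-1 strain also carries unc-119(ed3), and its unc-119 mRNA was 27.7 ± 3.35 at generation 1 against 97.8 ± 12.9 in the wild type and 58.1 ± 10.3 in the triple mutant, which lacks that allele. Every contrast with mut-14 smut-1 therefore also contrasts the unc-119 allele. No mRNA of prg-1(tm872) was analysed here, and its small RNAs mapping to prg-1 were 1685 ± 40.9 against 1447 ± 19.1 in the wild type, so that label had no check by mRNA.

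The wild-type libraries made with and without polyA selection asked which transcripts the selection loses. Core histone mRNAs, which end in a stem loop in place of a polyA tail, were almost absent after selection, with his-16 at 18.2 ± 9.82 against 16034 ± 3569 in total RNA. The log2 change was -9.79 ± 0.235 for his-16, -9.73 ± 0.221 for the identical pair his-12 and his-43, -9.41 ± 0.227 for his-45 and his-55, -7.79 ± 0.0947 for his-61 and -7.90 ± 0.0964 for his-58 and his-66. The histone genes his-37 and his-35 were slightly higher after selection, at 0.42 ± 0.0961 and 0.32 ± 0.1. Outside histones, T08B2.12 was higher by 8.35 ± 0.779, vha-9, encoding a vacuolar ATPase subunit, by 0.52 ± 0.0711 and nspd-10 by 0.58 ± 0.1002. Of 61 core histone genes tested, 2 higher and 58 lower (3 and 58) passed the limma test, with median -7.90, camera adjusted p = 3.61e-128 and 0.121. Of 47 transposon entries, 1 higher and 24 lower (1 and 26) passed, with median -0.73, camera adjusted p = 6.57e-11 and 0.121. In all, 797 of 14570 genes were higher and 1571 lower, and 7 and 395 of these changed 2-fold or more. The share of calls that were higher was 33.7%, and it was 23% with scaling by median ratios and 50.3% with library totals. Leaving out total RNA replicate 1 lowered the count of calls from 2368 to 1539. The call of his-35 was lost without polyA replicate 3 or total RNA replicate 1 or 2 (limma adjusted p of 0.176, 0.0961 and 0.107). All mutant mRNA libraries were made from rRNA-depleted RNA with no polyA selection, so core histone mRNAs can be read in them.

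Generation 1 small RNA of prg-1 asked which small RNAs change when the piRNA Argonaute is lost. Small RNAs against core histone genes rose, as the plot of core histone levels per library shows, and those against most F-box and MATH genes fell. The histone gene his-61 rose to 1708 ± 160.2 against 8.76 ± 0.486 in the wild type (adjusted p = 6.1e-10). The identical pair his-45 and his-55 rose to 472 ± 23.9 against 20.3 ± 0.179, while his-37 fell by 1.12 ± 0.259 on the log2 scale. Histone sequences took 2.76 ± 0.0524% of the counted total in prg-1 against 0.472 ± 0.00669% in the wild type (exact permutation p = 0.1, the smallest 3 against 3 can give). The largest gains elsewhere were in nex-2, an annexin gene (16047 ± 1184 against 6.59 ± 2.09), rabi-1 (10.63 ± 0.628), alh-7 (9.88 ± 0.612), mif-1 (9.23 ± 0.826) and the homeobox gene ceh-44 (30741 ± 1615 against 54.8 ± 5.82). The largest losses were in Y43D4A.6 (-7.98 ± 1.16), K08E5.1 (-7.74 ± 0.972), dot-1.5 (-7.72 ± 1.16) and got-1.2 (89.8 ± 118 against 9429 ± 33.2). Small RNAs of bath-45, fbxb-97 and xol-1, used in the field as readouts of piRNA silencing, dropped to 91.4 ± 83.0 against 7512 ± 92.0, to 37.6 ± 26.97 against 2188 ± 102 and to 3.17 ± 2.17 against 408 ± 17.1. Those of pals-22, a repressor of the intracellular pathogen response, dropped to 11.3 ± 10.2 against 952 ± 17.3. Among cuticle collagens, col-158 rose at least 533-fold from a wild type with no reads, dpy-17 rose by 6.02 ± 0.479 and col-60 fell (-4.68 ± 0.371). Among F-box and MATH genes, fbxc-40 was at least 39.4-fold lower with no reads left. Of 64 core histone genes, 55 higher and 1 lower (55 and 1) passed, with median 4.18, camera adjusted p = 8.63e-24 and 0.047. For the 164 F-box and MATH genes the counts were 20 higher and 116 lower (22 and 117), with median -2.66, camera adjusted p = 9.38e-07 and 0.0658. Smaller lists passed with the preset correlation alone: 18 cuticle collagens had 13 higher and 2 lower (15 and 2), median 1.61, camera adjusted p = 0.000598 and 0.0556, and the 8 ERGO-1 class targets, among them K02E2.6 at 1.33 ± 0.0684, had 7 higher and 0 lower (7 and 0), median 1.33, camera adjusted p = 0.00019 and 0.0842. The 5 pals genes had 0 higher and 4 lower (0 and 4), median -5.51, camera adjusted p = 0.0472 and 0.254. The 3 readout genes had 0 higher and 3 lower (0 and 3), median -6.71, camera adjusted p = 0.0472 and 0.254. The camera call of the pals and readout lists was lost when any of wild-type replicates 1, 2 and 3 or prg-1 replicate 2 was left out (adjusted p of 0.0507, 0.0505, 0.0515 and 0.0516 for pals, and 0.0507, 0.0502, 0.0515 and 0.0523 for the readouts). Both calls were also lost with library totals (adjusted p = 0.126 for each), the replicate block (0.0592 and 0.0574) and only the 2 groups (0.0531 each), and that of pals with DESeq2 (0.0803) and with no filter (0.138, median -0.47).

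Across 7418 genes with small RNAs, 2069 were higher and 2843 lower in prg-1, 798 and 2313 of them by 2-fold or more. In 4870 of the called genes the 3 prg-1 libraries did not overlap the 3 wild-type libraries, and 76.4% of all tested genes were so arranged, where chance gives 10%. The share of calls that were higher was 42.1%, and 14.7% with library totals, which moved the median of all genes from -0.10 to -0.67. Histone gene copies with identical values share reads, so their values are not separate measurements.

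The second allele, prg-1(tm872), asked whether these small RNA changes follow loss of prg-1 or the n4357 strain. Core histone small RNAs rose here too, with his-47, his-57 and his-65 at 2978 ± 228 against 35.5 ± 1.24 and his-37 falling (-3.19 ± 0.123). The annexin gene nex-2 rose to 19275 ± 193 against 17.5 ± 11.8, C07G1.7 by 10.50 ± 0.229 and ZK1098.11 by 8.49 ± 0.0778, and Y39F10C.2 rose at least 369.7-fold from no reads. The chitinase gene cht-2 was at least 246-fold lower, F22H10.4 fell by 8.54 on the log2 scale, nipi-4 was lower (-8.41 ± 0.478) and so was somi-1 (-8.33 ± 0.296). The readouts were lower again: fbxb-97 (-6.02 ± 0.202), bath-45 (-6.47 ± 0.229) and xol-1 (-7.07 ± 0.280), as were pals-22 (-6.92 ± 0.355) and fbxa-150 (-6.83 ± 0.138). The collagen genes col-111 and col-38 rose by 6.13 ± 0.0846 and 4.67 ± 0.112. Of 64 core histone genes the counts were 45 higher and 3 lower (45 and 3), with median 2.36, camera adjusted p = 7.57e-13 and 0.0728. The 159 F-box and MATH genes had 20 higher and 126 lower (21 and 127), median -3.43, camera adjusted p = 7.25e-09 and 0.221. Collagens had 15 higher and 3 lower (15 and 3), median 1.22, camera adjusted p = 0.00211 and 0.221. The 5 pals genes had 0 higher and 5 lower (0 and 5), median -5.78, camera adjusted p = 0.0117 and 0.221. The readouts had 0 higher and 3 lower (0 and 3), median -6.47, camera adjusted p = 0.0259 and 0.325. The pals call was lost with DESeq2 (adjusted p = 0.0771). Over 7273 genes, 2490 were higher and 3012 lower, and 5441 called genes had no overlap, with 78.8% of tested genes so arranged against 10% by chance. Higher calls made up 45.3%, and 30.7% with library totals, which moved the median from -0.05 to -0.30.

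The effects of the 2 alleles, from separate wild types, correlated across 7070 genes at r = 0.845 (Spearman 0.827), where genes are not independent replicates. Of 4192 genes called in both, 1565 were higher and 2447 lower in both and 180 opposite, where independent lists would share 660 and 1134. The difference itself, tm872 minus n4357, was called for 680 higher and 903 lower of 7561 genes. C48B6.9 (10.15 ± 0.597), T14G10.8 (9.34 ± 0.151) and the neuropeptide gene nlp-12 (9.15 ± 0.312) lay higher in tm872, and gst-43 (-12.07 ± 0.520), elmd-1 (-10.62 ± 0.237) and mif-1 (-9.59 ± 0.498) lower. The gain at core histones was smaller in tm872, with his-58 and his-66 at -3.77 ± 0.219 and his-15 at -4.08 ± 0.238, though his-17, his-27 and his-49 lay higher (1.42 ± 0.232). The core histone list had 5 higher and 48 lower (6 and 48), median -1.38, camera adjusted p = 1.13e-19 and 0.0426. F-box and MATH genes had 8 higher and 35 lower (11 and 39), median -0.34, camera adjusted p = 0.0186 and 0.396. ERGO-1 class targets had 0 higher and 7 lower (0 and 8), median -0.92, camera adjusted p = 0.000127 and 0.245, with W04B5.1 at -1.02 ± 0.132. The F-box call was lost without n4357 replicate 1 (adjusted p = 0.0531) and without the tm872 series' wild-type replicate 2 (adjusted p = 0.053), and with DESeq2 (0.285), no filter (0.216, median -0.15) and edgeR (0.0682). Of all calls, higher ones were 43%, and 74.1% with library totals, which moved the median from -0.01 to 0.30. The series also differ in age, 72 h against 68 h, so allele and age are contrasted together.

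Generation 50 small RNA asked what 50 generations without prg-1 left of each small RNA class. The piRNAs fell from 5.56 ± 0.245% of the counted total in the wild type to 0.0244 ± 0.00287% in prg-1, 228-fold, and 4352 of 4370 piRNAs tested were lower and 2 higher. Small RNAs of the authors' histone class rose from 0.0742 ± 0.00138% to 0.522 ± 0.0788% and those of the rRNA class from 0.0730 ± 0.00667% to 2.03 ± 0.346%, 27.8-fold (each exact permutation p = 0.1, the smallest possible). The mut class went from 41.5 ± 0.698% to 33.5 ± 2.51%, with 448 genes higher and 1487 lower, and the csr class had 1550 higher and 418 lower. These classes are the authors' own and may have been chosen on such samples, so their direction is not independent evidence. Among single genes ceh-44 rose to 55007 ± 17851 against 159 ± 9.94, his-47, his-57 and his-65 to 5640 ± 1284 against 35.1 ± 5.204, his-61 by 6.86 ± 0.273, his-43 by 6.60 ± 0.266 and C53D5.5 by 7.97 ± 0.243. The ribosomal RNA genes rrn-1.1 and rrn-1.2 rose to 15144 ± 1217 against 460.3 ± 62.7, and rrn-3.1 by 5.23 ± 0.238. Losses were led by C27C7.7 (-9.88 ± 0.511), nipi-4 (-9.79 ± 0.753), the Notch ligand gene lag-2 (-9.41 ± 0.545) and pals-22 (-8.44 ± 0.409). The readout bath-45 was lower (-7.13 ± 0.222), as were fbxb-97 (-3.05 ± 0.127) and xol-1 (-8.38 ± 0.353), and of the F-box and MATH genes fbxc-43 (-8.195 ± 0.214) fell and math-50 (5.47 ± 0.327) rose. Among miRNAs, let-7-5p rose by 1.99 ± 0.253 and miR-77-5p by 2.32 ± 0.228, and miR-78 fell (-5.13 ± 0.366).

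Of 73 core histone entries at generation 50 the counts were 56 higher and 0 lower (56 and 0), with median 3.25, camera adjusted p = 3.19e-27 and 0.111, and all 4 rRNA entries rose (4 higher and 0 lower (4 and 0)), with median 5.04, camera adjusted p = 0.000165 and 0.111. The 191 transposons had 70 higher and 32 lower (67 and 26), median 0.08, camera adjusted p = 1.89e-08 and 0.111, with WBTransposon00000216 higher by 2.22 ± 0.150 and WBTransposon00000113 lower (-6.04 ± 0.380), and their median turned negative with library totals (-0.32), miRNA scaling (-0.60), TMM (-0.35), edgeR (-0.39) and without prg-1 line 3 (-0.04). The call was lost in a fit without piRNAs and miRNAs (adjusted p = 0.227). The share of transposons in the total went from 1.93 ± 0.0366% to 2.81 ± 0.156% with no overlap, 1.46-fold, and it was 1.38-fold without piRNAs and 1.2-fold per miRNA count (each exact permutation p = 0.1). F-box and MATH genes (26 higher and 89 lower (26 and 89), median -2.52, camera adjusted p = 0.643), pals genes (0 higher and 5 lower (0 and 5), median -4.51, camera adjusted p = 0.191) and the readouts (0 higher and 3 lower (0 and 3), median -7.13, camera adjusted p = 0.0716) did not pass. The 3 lists passed with DESeq2 (adjusted p of 0.00145, 0.0105 and 2.93e-07) and without piRNAs and miRNAs (1.36e-06, 0.0156 and 0.00492). The readouts passed with no filter (0.0112) and without prg-1 line 2 or 3 (0.0429 and 0.0466). Of 10968 features, 2339 were higher and 6288 lower, and among the 6363 that were neither piRNAs nor miRNAs 2231 and 1917 were. Called features with no overlap numbered 8465, and 82.3% of the tested ones were so arranged, against 10% by chance. Calls that were higher made up 27.1%, and 11.8%, 7.56% and 12.7% with library totals, miRNA scaling and TMM, which moved the median from -1.84 to -2.15, -2.51 and -2.20. Between generations 1 and 50 the prg-1 effect correlated across 5109 genes at r = 0.895, and of 2772 genes called in both 1308 were higher, 1407 lower and 57 opposite (575 and 528 if independent). The difference between generations was called for 167 higher and 321 lower of 5435 genes, with math-48 (9.10 ± 0.599), Y52B11A.19 (8.999 ± 0.475) and math-50 (6.41 ± 0.407) more raised at generation 50 and idpp-2 (-10.1 ± 0.719) and nmtn-1 (-9.44 ± 0.141) less. The core histone gain did not differ, with 0 higher and 0 lower (0 and 0) of 53 genes, median -0.33, camera adjusted p = 0.076, though the list passed without generation 50 wild-type line 1 (median -0.46) or prg-1 line 2 (-0.42), and its median was 0.06 without prg-1 line 1. Higher calls in this difference made up 34.2%, and 66.9% with library totals, which moved the median from 0.02 to 0.27.

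Small RNAs of mut-14 smut-1 asked which genes need the mutator helicases for their small RNAs. At generation 1 the loss was wide: fbxb-14 fell to 103 ± 3.61 against 4599 ± 116 (n = 2 mutant libraries), pals-22 was lower (-7.32 ± 0.707), and K10F12.6 and the GABA receptor gene unc-49 were at least 430-fold and at least 338-fold lower, with no reads in the mutant. Y53F4B.17 (-10.19 ± 1.27) and glb-14 (-9.197 ± 1.33) fell as well, and the histone copies his-50 and his-28 were at least 15.2-fold lower, while his-63 rose by 0.71 ± 0.112. The sperm gene spch-1 rose to 47 ± 14.3 against 2.07 ± 2.31, the cell death gene egl-1 by 3.39 ± 0.341 and the eggshell genes egg-4 and egg-5 by 0.70 ± 0.0683 and 0.65 ± 0.0557. At generation 50 the histone demethylase gene jmjd-3.1 fell to 17.4 ± 3.93 against 9457 ± 847, glb-14 fell (-9.06 ± 0.556), and so did nhr-58 (-9.27 ± 0.615), fbxa-61 (-8.10 ± 0.183) and col-60 (-7.18 ± 0.275). WBTransposon00000275 fell to 64.5 ± 6.31 against 10126 ± 754, and all transposons together from 1.93 ± 0.0366% to 0.0314 ± 0.00570% of the total. The sperm gene spch-1 rose again (4.59 ± 0.867), as did F10C1.3 (4.77 ± 0.632) and the histone gene his-72 (1.82 ± 0.207, but not called at 0.47 with miRNA scaling), and his-54 fell (-3.74 ± 0.453). The mut class went from 41.5 ± 0.698% to 1.43 ± 0.0198%, with 2 genes higher and 2387 of 2431 lower, and the piRNA share was 9.68 ± 2.40%. At generation 1, 5 higher and 144 lower (5 and 145) of 164 F-box and MATH genes passed (median -4.16, camera adjusted p = 2.02e-11 and 0.0401; -3.74 with genes at no reads set to their bound). Collagens had 0 higher and 16 lower (1 and 16), median -3.49, camera adjusted p = 0.00373 and 0.0733 (bounded median -3.05). Pals genes had 0 higher and 5 lower (0 and 5), median -6.61, camera adjusted p = 0.0204 and 0.167 (bounded median -5.77). Oocyte and eggshell genes had 17 higher and 0 lower (17 and 0), median 0.58, camera adjusted p = 2.61e-07 and 0.00983. With DESeq2 and with no filter the calls were lost for collagens (adjusted p = 0.106 for each, median -0.49 with no filter) and pals genes (0.0657 and 0.126, median -0.62 with no filter). Core histones had 10 higher and 26 lower (7 and 26), median -0.63, camera adjusted p = 0.536, and their median was 0.27 with library totals, but summed they were called (-1.02, 8.65e-06). At generation 50 transposons had 0 higher and 186 lower (0 and 186), median -5.81, camera adjusted p = 1.82e-48 and 0.000476. F-box and MATH genes had 6 higher and 135 lower (6 and 135), median -5.13, camera adjusted p = 2.3e-29 and 0.000476. Collagens had 0 higher and 10 lower (0 and 10), median -6.02, camera adjusted p = 1.6e-06 and 0.00566. Core histones had 4 higher and 45 lower (4 and 45), median -1.27, camera adjusted p = 7.84e-07 and 0.501, a call lost with DESeq2 (0.0602) and without piRNAs and miRNAs (0.0693), and pals genes 0 higher and 5 lower (0 and 5), median -6.44, camera adjusted p = 0.000987 and 0.166.

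In mut-14 smut-1, 1621 genes were higher and 3476 lower of 7418 at generation 1, and 5789 and 2848 of 10968 features at generation 50 (2138 and 2835 among those that were neither piRNAs nor miRNAs). At generation 50, 85.2% of tested features had no overlap between groups, where chance gives 10%. Higher calls made up 31.8% at generation 1, and 60.4% with library totals (median -0.47 to 0.62). At generation 50 they made up 67%, and 48.5%, 18.7% and 40.8% with library totals, miRNA scaling and TMM (medians 0.66, 0.25, -0.68 and 0.02). Genes that lost small RNAs 4-fold or more in mut-14 smut-1 were mostly lower in prg-1 where read in the other generation, with no wild type shared. Of 2210 defined at generation 50, 1559 were read at generation 1: 1120 (71.8%) lower, 240 higher (3550 others: 14.6% lower). Of 2365 defined at generation 1, 1623 were read at generation 50: 1198 (73.8%) lower, 208 higher (3486 others: 12.9%). Generation 50 genes were of the authors' classes, so this is not independent evidence.

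The triple mutant asked whether the small RNA gains of prg-1 need the mutator helicases, and what loss of prg-1 adds in their absence. The gain at histones was absent: at generation 1 the effect of prg-1 on his-61 was different between the mut-14 smut-1 background and the wild type by -7.76 ± 0.252, and that on his-45 by -3.88 ± 0.148. At generation 50 the same difference was -7.84 ± 0.376 for his-47, his-57 and his-65, -5.14 ± 0.337 for rrn-3.1 and -4.30 ± 0.311 for rrn-1.1. In mut-14 smut-1 at generation 1 (n = 2 libraries), the readout bath-45 had already fallen to 138 ± 10.6 against 7512 ± 92.0 in the wild type, which left less room for a further loss. Differences between backgrounds were 5.29 ± 1.03 for bath-45, 6.33 ± 0.789 for fbxb-97 and 7.41 ± 0.811 for xol-1 at generation 1, and 5.45 ± 0.315, 3.06 ± 0.180 and 7.64 ± 0.499 at generation 50. Directly against mut-14 smut-1, the triple mutant had more small RNAs of suco-1 (1.96 ± 0.248) and haf-6 (1.81 ± 0.326) at generation 1 and of suco-1 (1.51 ± 0.137) and the vitellogenin genes vit-2 (1.62 ± 0.599) and vit-1 (1.46 ± 0.522) at generation 50. It had fewer of Y53F4B.5 (-3.72 ± 0.789 and -4.68 ± 0.257), fbxa-203 (-3.74 ± 0.754 and -3.24 ± 0.289), C16C8.16 at generation 1 (-4.05 ± 0.459) and T26E3.7 at generation 50 (-4.17 ± 0.294). At generation 1 the calls were lost for Y53F4B.5 without mut-14 smut-1 replicates 1 and 2 and triple mutant replicates 1 and 2 (limma adjusted p of 0.135, 0.0521, 0.0631 and 0.0678). Those of fbxa-203 and haf-6 were lost without mut-14 smut-1 replicate 1 (0.107 and 0.0861), and that of fbxa-203 without triple mutant replicate 1 (0.0508). In a fit of only the 2 groups none of the 5 was called: suco-1 (0.14), haf-6 (0.217), C16C8.16 (0.121), Y53F4B.5 (0.196) and fbxa-203 (0.129). At generation 50 vit-1 and vit-2 lost theirs without mut-14 smut-1 line 1 (0.12 and 0.139, at 0.76 and 0.80) and triple mutant lines 1 (0.0936 and 0.121) and 3 (0.0684 and 0.0883), and vit-1 without line 2 (0.0561). Against the wild type the triple mutant lost fbxb-14 (-6.73 ± 0.178), got-1.2 (-9.88 ± 1.41) and bath-20 (-9.54 ± 1.18) at generation 1 and nipi-4 (-10.59 ± 0.753), bath-11 (-8.17 ± 0.142) and WBTransposon00000216 (-7.30 ± 0.150) at generation 50. It gained ssp-16 (3.83 ± 0.397) at generation 1 and rpn-8 (2.40 ± 0.148) at generation 50. Its piRNA share was 0.0318 ± 0.00357%, its mut class 1.19 ± 0.0867%, and its histone class 0.0117 ± 0.00147% against 0.00972 ± 0.00175% in mut-14 smut-1 (exact permutation p = 0.2).

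The test of that difference gave core histones 0 higher and 56 lower (0 and 56) at generation 1, median -4.10, camera adjusted p = 7e-28 and 0.0612, and 0 higher and 56 lower (0 and 56) at generation 50, median -3.46, camera adjusted p = 3.41e-11 and 0.219. F-box and MATH genes, already low in mut-14 smut-1, had 102 higher and 17 lower (104 and 18), median 2.61, camera adjusted p = 1.74e-06 and 0.0839, and 81 higher and 25 lower (82 and 29), median 2.15, camera adjusted p = 1.61e-13 and 0.0075. The rRNA genes at generation 50 had 0 higher and 4 lower (0 and 4), median -4.30, camera adjusted p = 0.00946 and 0.219. Against mut-14 smut-1, core histones at generation 1 had 2 higher and 3 lower (3 and 6), median -0.17, camera adjusted p = 0.194, and their median was -0.32 and passed (adjusted p = 0.0231) without triple mutant replicate 1. At generation 50 F-box and MATH genes had 5 higher and 39 lower (2 and 27), median -0.59, camera adjusted p = 0.0012 and 0.0907. Camera ranked them, though lower, above the other features, of which 4360 of 4370 piRNAs fell (median -5.65). The stricter filter ended the call (0.342). Against the wild type, core histones had 8 higher and 38 lower (8 and 43), median -1.22, camera adjusted p = 0.112, at generation 1 (called with no filter, 0.0425, and when summed, -1.19 and 8.82e-07) and 8 higher and 50 lower (8 and 50), median -1.72, camera adjusted p = 0.746, at generation 50, where camera's direction was up against a negative median and the sum was called (-1.83, 6.68e-08). F-box and MATH genes had 7 higher and 146 lower (7 and 147), median -4.38, camera adjusted p = 7.23e-11 and 0.0273, and 7 higher and 135 lower (8 and 135), median -5.38, camera adjusted p = 4.84e-05 and 0.0411. Transposons had 0 higher and 191 lower (0 and 191), median -6.12, camera adjusted p = 1.97e-11 and 0.0341. Triple against mut-14 smut-1 gave 215 higher and 236 lower genes at generation 1, 171 and 681 calls without mut-14 smut-1 replicate 1 and 2, and 664 and 5327 features at generation 50, of which 650 and 957 were neither piRNAs nor miRNAs. Against the wild type the counts were 1774 and 3689, and 2385 and 7207. Higher calls made up 32.5% at generation 1, and 58% with library totals (median -0.54 against 0.52). At generation 50 they made up 24.9%, and 15.4%, 2.38% and 14.1% with library totals, miRNA scaling and TMM (median -2.92 against -3.19, -3.87 and -3.30), and TMM moved the median against mut-14 smut-1 from -0.71 to -0.53.

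**Figure D1:**
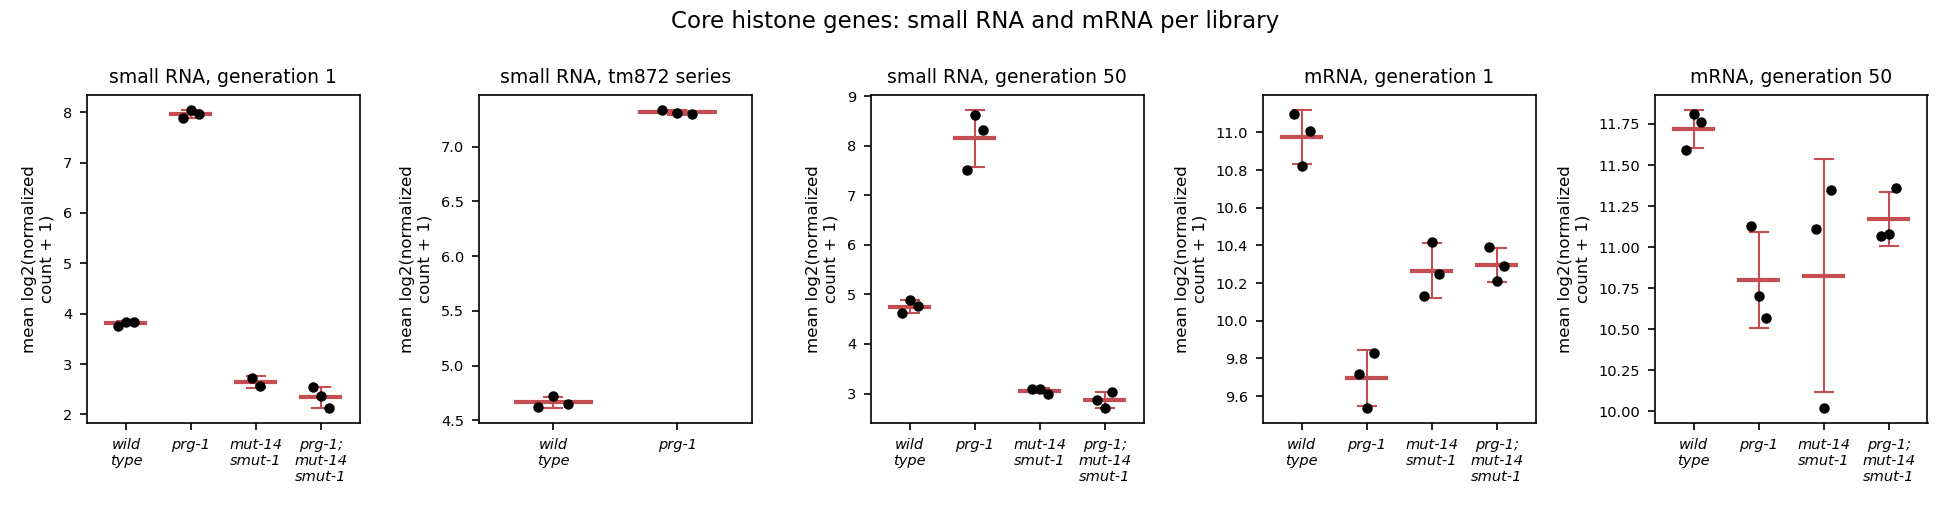
Mean log2(normalized count + 1) over core histone genes (vertical axis) for each library, with the group mean as a bar and the SD as error bars, for small RNA and mRNA and each genotype (horizontal axis). Small RNA means of the 3 prg-1 libraries lie above those of the wild type in each series, with median log2 changes of 4.18, 2.36 and 3.25, and mRNA group means of prg-1 lie below.

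**Figure D2:**
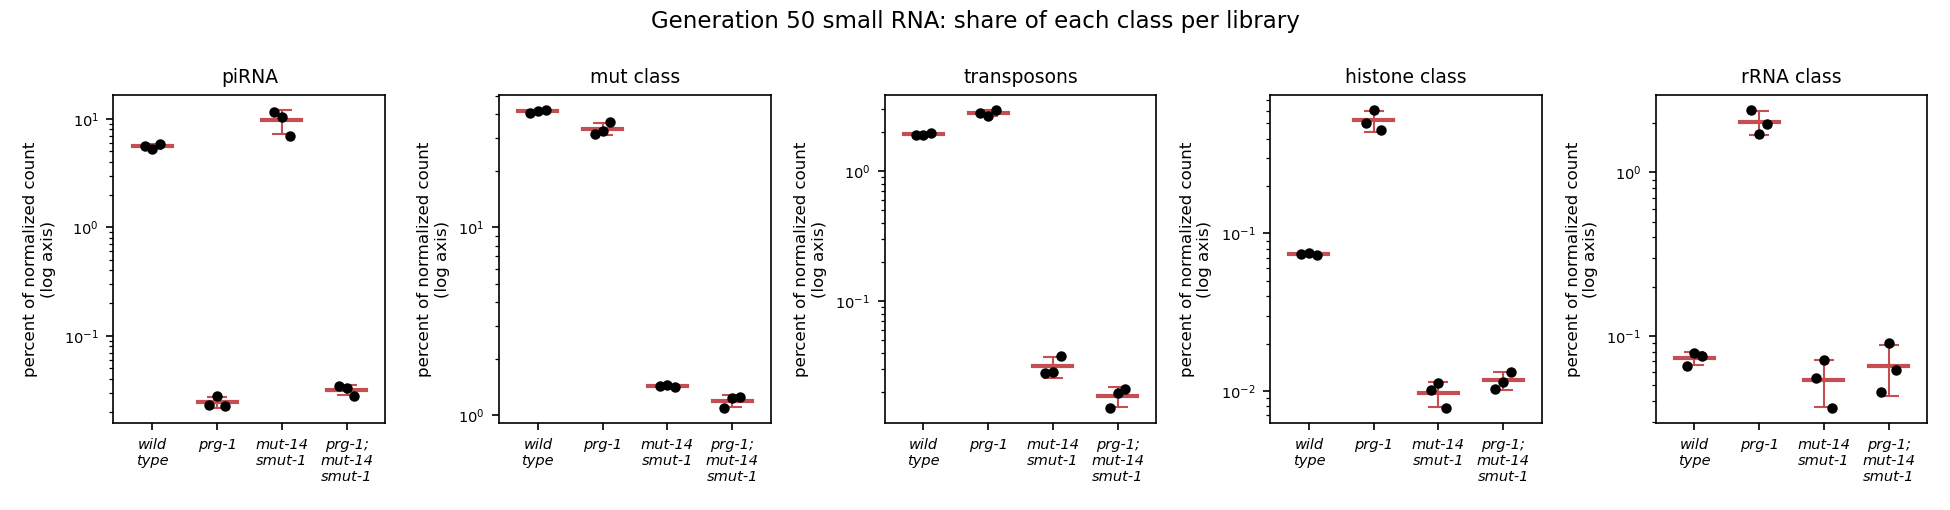
Percent of the normalized count taken by each small RNA class (vertical log axis) in each generation 50 library, by genotype (horizontal axis), with the group mean as a bar and the SD as error bars. The piRNA share was 5.56% in the wild type and 0.0244% in prg-1, and the rRNA class 0.0730% and 2.03%.

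Generation 1 mRNA of prg-1 asked which transcripts differ between that strain and the wild type. Transcripts of sperm and cuticle genes rose and those of core histones fell. The major sperm protein gene msp-36 rose to 265 ± 4.62 against 53.97 ± 6.11, the sperm fusion gene fer-1 to 82.1 ± 9.34 against 14.3 ± 0.282, and the collagen genes col-13 and col-133 by 1.72 ± 0.140 and 1.52 ± 0.111. The readouts bath-45 and fbxb-97 rose to 1058 ± 39.9 against 56.4 ± 5.03 and to 457 ± 11.07 against 33.2 ± 5.21, and xol-1 was not called (0.25 ± 0.183, limma adjusted p = 0.25). The largest gains were in R09E10.2 (6.49 ± 0.175), Y23H5A.8 (5.67 ± 0.139), the mitochondrial import gene timm-17B.2 (5144 ± 239.9 against 119.6 ± 15.1) and the glutathione peroxidase gene gpx-8 (4.37 ± 0.233). The largest losses were in C27C7.1 (16.6 ± 3.74 against 739 ± 38.4), the zinc finger gene ztf-28 (22 ± 4.97 against 542 ± 21.2) and the identical histone copies his-10, his-14 and his-26 (242 ± 34.2 against 2633 ± 276). Oocyte transcripts fell less, with the yolk receptor gene rme-2 at 24687 ± 882 against 34296 ± 1576 and nos-2 at -0.60 ± 0.0551, while egg-4 rose by 0.38 ± 0.0546. The meiotic axis genes htp-3 and him-3 fell by 0.43 and 0.29 on the log2 scale, as did the small RNA amplification factors rde-2 and drh-3 by 0.44 and 0.43, while rde-11 rose by 0.75 ± 0.0512. Core histones had 1 higher and 54 lower (1 and 54) of 63, median -1.098, camera adjusted p = 2.86e-22 and 0.256. Major sperm protein genes had 31 higher and 0 lower (31 and 0), median 1.94, camera adjusted p = 2.17e-22 and 0.133. Other spermatogenesis genes had 26 higher and 1 lower (26 and 1), median 1.55, camera adjusted p = 2.84e-11 and 0.0966. Collagens had 105 higher and 2 lower (106 and 2), median 0.90, camera adjusted p = 1.88e-18 and 0.0436. Oocyte and eggshell genes had 1 higher and 21 lower (1 and 21), median -0.28, camera adjusted p = 3.99e-05 and 0.491. Germline proliferation and meiosis genes had 0 higher and 22 lower (0 and 22), median -0.22, camera adjusted p = 9.25e-05 and 0.435. Mutator factors had 2 higher and 21 lower (2 and 21), median -0.28, camera adjusted p = 0.000133 and 0.435. The readouts had 2 higher and 0 lower (2 and 0), median 3.75, camera adjusted p = 0.000652 and 0.0843. Of 14618 genes, 3736 were higher and 4678 lower, 1529 and 281 by 2-fold or more, and 7924 calls had no overlap (61.2% of tested genes, 10% by chance). Higher calls made up 44.4%, and 62.7% and 55% with library totals and TMM, which moved the median of all genes from -0.02 to 0.10 and 0.05, and 27.6% with the stricter filter (median -0.17). Major sperm protein genes are near-identical, so their reads cannot be told apart, and counting by strand is not stated, so an antisense partner cannot be told apart.

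Genes with small RNA and mRNA changes were set side by side, asking whether mRNA moved opposite to small RNA in prg-1. At generation 1, 429 of 6970 genes had lower small RNA and higher mRNA, among them Y53F4B.5 (-7.06 ± 0.706 and 5.79 ± 0.362), T26E3.7 (-7.56 ± 1.04 and 5.23 ± 0.141) and bath-45 (-6.71 ± 0.689 and 4.21 ± 0.0758). The share with higher mRNA was 16.6% of genes with lower small RNA and 6.94% of the rest (odds ratio 2.66, Fisher's exact adjusted p = 1.15e-34). More genes, 1153, had lower small RNA and lower mRNA, and 180 had both higher. At generation 50 these counts were 69 and 31. In the other direction, ztf-28 (6.45 ± 0.225 and -4.58 ± 0.131), nssp-7 (9.17 ± 0.479 and -3.17 ± 0.133) and C27C7.1 (5.29 ± 0.128 and -5.41 ± 0.107) gained small RNA and lost mRNA, as did 45 of 62 core histone genes. Of genes with higher small RNA 61.9% had lower mRNA, against 54.7% of the rest (odds ratio 1.34, adjusted p = 9.35e-08), and with calls of 2-fold or more the ratio was 8.26. At generation 50, B0250.8 (-8.36 ± 0.202 and 5.43 ± 0.476), Y53F4B.5 (mRNA 5.91 ± 0.328), bath-45 (-7.13 ± 0.222 and 4.87 ± 0.211) and col-60 (-6.35 ± 0.275 and 5.06 ± 0.834) were among 153 of 5528 genes with lower small RNA and higher mRNA (8.81% against 1.71%, odds ratio 5.53, adjusted p = 1.12e-32). Lower mRNA at higher small RNA was seen in 29 genes there, 12 of them among 52 core histones, or 1.54% against 3.46% of the rest (odds ratio 0.436, adjusted p = 2.20e-05), and with calls of 2-fold or more the ratio was 5.52. Across all genes the 2 changes correlated at r = -0.194 (Spearman -0.124) at generation 1 and at -0.106 (Spearman 0.0331) at generation 50.

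Generation 50 mRNA asked which changes remained in lines kept without prg-1. The readouts bath-45 and fbxb-97 stayed high, at 2202 ± 518 against 73.9 ± 12.5 and 3.77 ± 0.175 on the log2 scale, and xol-1 was not called (0.04 ± 0.307, limma adjusted p = 0.96). The sperm calcium channel gene spe-41 rose to 464 ± 134 against 92.3 ± 30.4, spe-8 by 4.11 ± 0.659 and msp-64 by 5.22 ± 1.31. The cuticle genes rol-1, bli-6 and col-88 rose by 7.30 ± 0.650, 6.19 ± 0.883 and 5.77 ± 0.589, and R09E10.2 by 7.995 ± 0.652. R05A10.1 (-5.89 ± 0.514), ztf-28 (-4.06 ± 0.467), dpy-6 (-3.28 ± 0.421), C27C7.1 (-3.06 ± 0.376) and col-10 (-3.03 ± 0.365) fell, and so did the histone genes his-54 (432 ± 219 against 3275 ± 1185) and his-11 (-1.41 ± 0.260). The synaptic genes rab-3 and snt-1 fell by 1.22 and 1.11 on the log2 scale. Spermatogenesis genes had 18 higher and 0 lower (24 and 0) of 30, median 2.60, camera adjusted p = 6.57e-12 and 0.45. Major sperm protein genes had 14 higher and 0 lower (29 and 0), median 4.495, camera adjusted p = 1.67e-11 and 0.731. Collagens had 54 higher and 14 lower (63 and 20), median 0.86, camera adjusted p = 1.33e-06 and 0.888. The major sperm protein median was 2.46 without wild-type line 2 and 6.22 without line 1. Core histones had 0 higher and 15 lower (0 and 27), median -0.89, camera adjusted p = 1.03e-14 and 0.45, but as one summed feature they changed by -0.47 with no call (0.0595). Neuropeptide and synapse genes had 0 higher and 5 lower (0 and 9), median -0.58, camera adjusted p = 4.47e-07 and 0.285. The readouts had 2 higher and 0 lower (2 and 0), median 3.77, camera adjusted p = 8.47e-05 and 0.0799. Of 16328 genes 1210 were higher and 621 lower, and 1739 calls had no overlap (34.8% of tested genes, 10% by chance). The call of msp-64 was lost without wild-type lines 2 and 3 (limma adjusted p of 0.065 and 0.0985) and prg-1 lines 1, 2 and 3 (0.068, 0.103 and 0.0531). The 1831 calls became 603 and 435 without wild-type lines 2 and 3 and 1031, 523 and 1206 without prg-1 lines 1, 2 and 3. The plot of sperm, collagen and oocyte genes shows each line.

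The generation 1 and 50 effects on mRNA correlated across 14586 genes at r = 0.65 (Spearman 0.4), and of 1383 genes called in both 1014 were higher, 225 lower and 144 opposite (301 and 173 if independent). The difference between generations was called for 1402 higher and 846 lower of 15440 genes. The cuticle gene rol-1 (5.97 ± 0.840) was raised more at generation 50, and R05A10.1 (-6.07 ± 0.815) and col-10 (-4.12 ± 0.405) less or lowered. The histone pair his-12 and his-43 was lowered less (1.67 ± 0.267), the synaptonemal gene syp-1 differed by 0.59 ± 0.0914, and the neuronal genes egl-3 and snt-1 by -1.54 ± 0.191 and -1.53 ± 0.199. Neuropeptide and synapse genes had 0 higher and 11 lower (0 and 13) of 17, median -1.03, camera adjusted p = 1.73e-11 and 0.197. Germline proliferation and meiosis genes had 11 higher and 0 lower (17 and 0), median 0.35, camera adjusted p = 9.72e-06 and 0.433. Core histones had 12 higher and 1 lower (13 and 1), median 0.20, camera adjusted p = 0.0126 and 0.758. The core histone call was lost without generation 1 wild-type replicate 1 (adjusted p = 0.0553), generation 50 wild-type line 1 (0.0597) and prg-1 line 1 (0.163), with the stricter filter (0.551) and with core histones summed as one feature (0.189). The 2248 calls became 727, 845 and 1222 without generation 1 wild-type replicates 1, 2 and 3, 1034, 870 and 942 without prg-1 replicates 1, 2 and 3, and 4087 without generation 50 prg-1 line 1. Higher calls made up 62.4%, and 50.9%, 16.6% and 34.7% with median ratios, library totals and TMM, which moved the median from 0.16 to 0.11, -0.01 and 0.07. The generations were separate experiments, and no hours of age were given for generation 50, so generation and experiment are contrasted together.

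**Figure D3:**
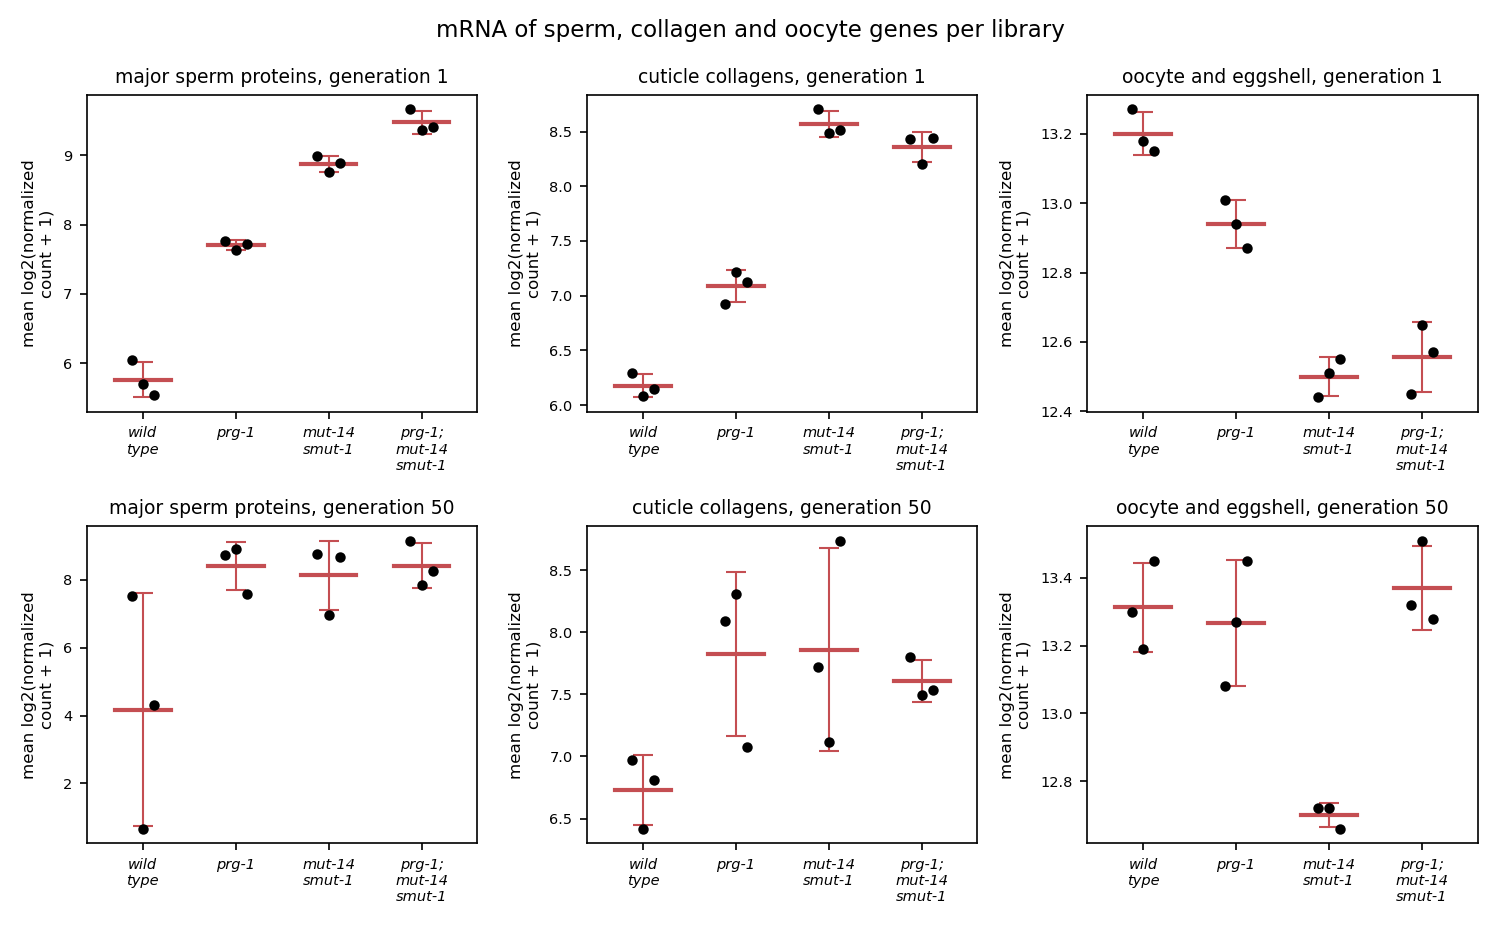
Mean log2(normalized count + 1) over major sperm protein, cuticle collagen and oocyte genes (vertical axis) in each mRNA library of generations 1 and 50 by genotype (horizontal axis), with the group mean as a bar and the SD as error bars. At generation 1 the median log2 changes of major sperm protein genes were 1.94, 3.14 and 3.76 in prg-1, mut-14 smut-1 and the triple mutant, and at generation 50 the wild-type lines spread widely.

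The mRNA of mut-14 smut-1 and of the triple mutant asked what loss of mutator small RNAs does to transcripts and what loss of prg-1 adds to it. In mut-14 smut-1 at generation 1, C38D9.2 rose to 4053 ± 202 against 18.4 ± 3.22, sosi-1 rose by 6.53 ± 0.123, and WBTransposon00000098, listed at 0 in the wild type, stood at 292 ± 18.2. The sperm gene msp-36 rose by 3.66 ± 0.0912, the collagen gene col-133 by 3.60 ± 0.111, the ERGO-1 class targets C44B11.6 and K02E2.6 by 2.17 ± 0.305 and 1.24 ± 0.118, and the readouts fbxb-97 and bath-45 by 3.39 ± 0.106 and 2.38 ± 0.0758. Y73B3A.1 (-5.38 ± 0.240), ZK856.7 (-4.10 ± 0.126), haf-6 (-2.48 ± 0.0678) and eri-7 (-2.23 ± 0.0713) fell, with nos-2 (-1.105 ± 0.0551), cpg-3 (-1.03 ± 0.0561), the meiotic gene pch-2 (-0.90 ± 0.0509) and the histone pair his-28 and his-50 (-1.49 ± 0.0941). At generation 50 C38D9.2 (8.09 ± 0.351), rol-1 (7.56 ± 0.650), spe-8 (4.22 ± 0.659), fbxb-97 (3.61 ± 0.175), bath-45 (3.38 ± 0.211), pals-6 (2.44 ± 0.422) and W04B5.1 (2.96 ± 0.502) rose, and rme-2 (-1.03 ± 0.145), puf-5 (-0.98 ± 0.142), ZK856.7 (-3.55 ± 0.242) and his-54 (-3.07 ± 0.453) fell. At generation 1 major sperm protein genes had 31 higher and 0 lower (31 and 0), median 3.14, camera adjusted p = 3.53e-17 and 0.215. Collagens had 9 genes not called (120 and 5), median 2.90, camera adjusted p = 2.56e-22 and 0.0221. Core histones had 4 higher and 43 lower (4 and 43), median -0.67, camera adjusted p = 2.79e-06 and 0.422. Oocyte and eggshell genes had 0 higher and 26 lower (0 and 26), median -0.68, camera adjusted p = 1.64e-09 and 0.234. Germline proliferation and meiosis genes had 0 higher and 31 lower (0 and 31), median -0.53, camera adjusted p = 1.5e-08 and 0.217. The ERGO-1 class targets had 6 higher and 0 lower (6 and 0), median 0.93, camera adjusted p = 0.0221 and 0.215. The readouts had 2 higher and 0 lower (2 and 0), median 2.38, camera adjusted p = 0.0275 and 0.215. At generation 50 spermatogenesis genes had 19 higher and 0 lower (25 and 0), median 2.79, camera adjusted p = 9.6e-08 and 0.47. Oocyte genes had 0 higher and 16 lower (0 and 19), median -0.63, camera adjusted p = 6.5e-09 and 0.382. Pals genes had 14 higher and 0 lower (15 and 0), median 1.36, camera adjusted p = 8.99e-05 and 0.153. The ERGO-1 class targets had 5 higher and 0 lower (5 and 0), median 1.51, camera adjusted p = 0.00224 and 0.382. The readouts had 2 higher and 0 lower (2 and 0), median 3.38, camera adjusted p = 0.00265 and 0.153. Core histones had 0 higher and 23 lower (2 and 25), median -0.33, camera adjusted p = 0.000456 and 0.561, whose median was 0.03 without mut-14 smut-1 line 2 and which summed to -0.06 with no call (0.778). Counts were 5570 higher and 5836 lower at generation 1, and 2695 and 1843 at generation 50, whose 4538 calls became 2432 without wild-type line 3. Higher calls at generation 1 made up 48.8%, 61.5% with library totals and 28.9% with the stricter filter (median -0.33), and the median moved from 0.04 to 0.25 with library totals and 0.14 with TMM, while at generation 50 the share went from 59.4% to 69.4% with library totals.

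Against the wild type, the triple mutant at generation 1 had msp-64 (4.54 ± 0.115), bath-45 (3.99 ± 0.0758), fbxb-97 (3.85 ± 0.106) and xol-1 (0.83 ± 0.183) higher. Against mut-14 smut-1, F16B4.6 (4.63 ± 0.364), faah-5 (3.65 ± 0.167), B0250.8 (3.35 ± 0.168), bath-45 (1.61 ± 0.0758) and msp-36 (0.58 ± 0.0912) were higher, and again at generation 50 F16B4.6 (3.21 ± 0.450), faah-5 (2.92 ± 0.343), B0250.8 (2.96 ± 0.476) and bath-45 (0.97 ± 0.211), with the oocyte genes egg-5 (1.23 ± 0.114) and oma-1 (0.96 ± 0.133). C16C8.16 was listed at 0 in all 3 triple mutant libraries at generation 1, against 923 ± 6.58 in mut-14 smut-1, and differed by -10.54 ± 0.193 at generation 50, with C16C8.14 (-8.72 ± 0.337). The effect of prg-1 differed between backgrounds at generation 1 by 2.47 ± 0.123 for his-10, his-14 and his-26, -1.699 ± 0.129 for msp-36, -1.92 ± 0.157 for col-133, -2.60 ± 0.107 for bath-45 and -3.29 ± 0.150 for fbxb-97. At generation 50 it differed by 3.93 ± 0.640 for his-54, -3.90 ± 0.298 for bath-45 and -3.31 ± 0.247 for fbxb-97. In that test at generation 1, core histones had 54 higher and 1 lower (56 and 1), median 1.29, camera adjusted p = 1.78e-29 and 0.199. Major sperm protein genes had 0 higher and 28 lower (0 and 30), median -1.34, camera adjusted p = 1.95e-18 and 0.199. Collagens had 3 higher and 98 lower (3 and 102), median -1.19, camera adjusted p = 1.64e-24 and 0.017. The readouts had 0 higher and 2 lower (0 and 2), median -2.60, camera adjusted p = 0.00311 and 0.159. At generation 50 core histones had 4 higher and 0 lower (29 and 0), median 1.19, camera adjusted p = 2.55e-13 and 0.307, but 0.65 and no call when summed (0.0794) and a median of 0.59 without mut-14 smut-1 line 2, and the readouts 0 higher and 2 lower (0 and 2), median -3.31, camera adjusted p = 0.0031 and 0.184. In the triple mutant against the wild type at generation 1, core histones had 7 higher and 35 lower (7 and 35), median -0.95, camera adjusted p = 0.000274 and 0.563. Summed as one feature they changed by -0.12 (adjusted p = 0.234), and the stricter filter also ended the call (0.255). Major sperm protein genes there had 31 higher and 0 lower (31 and 0), median 3.76, camera adjusted p = 2.33e-18 and 0.168. Readouts had 3 higher and 0 lower (3 and 0), median 3.85, camera adjusted p = 0.00602 and 0.152. At generation 50 its spermatogenesis genes had 19 higher and 0 lower (24 and 0), median 2.81, camera adjusted p = 1.71e-10 and 0.543. Readouts had 2 higher and 0 lower (3 and 0), median 4.07, camera adjusted p = 9.3e-06 and 0.039. Against mut-14 smut-1 at generation 1, the major sperm protein genes had 24 higher and 0 lower (28 and 0), median 0.59, camera adjusted p = 3.22e-17 and 0.231. The readouts had 3 higher and 0 lower (3 and 0), median 0.74, camera adjusted p = 3.05e-05 and 0.047. At generation 50 the oocyte genes had 10 higher and 0 lower (22 and 0), median 0.63, camera adjusted p = 6.12e-17 and 0.133. The readouts had 1 higher and 0 lower (3 and 0), median 0.80, camera adjusted p = 0.0117 and 0.139, a call lost with the stricter filter (0.107), with a median of 0.53 without mut-14 smut-1 line 1. Higher and lower calls in the triple mutant numbered 5510 and 5648 against the wild type and 879 and 805 against mut-14 smut-1 at generation 1, and 1508 and 609, and 230 and 89, at generation 50. Without mut-14 smut-1 replicate 2 or 3 the 1684 calls of the generation 1 comparison with mut-14 smut-1 became 1107 and 1059. The 2117 generation 50 calls against the wild type became 872 and 670 without wild-type lines 2 and 3 and 581, 1035 and 600 without triple mutant lines 1, 2 and 3. At generation 50 the calls of bath-45 and B0250.8 against mut-14 smut-1 were lost without triple mutant lines 1, 2 and 3 (limma adjusted p of 0.139, 0.126 and 0.123, and 0.0695, 0.0614 and 0.0625). That of bath-45 was also lost without mut-14 smut-1 lines 1 and 2 (0.0871 and 0.0625), and that of F16B4.6 without triple mutant line 1 (0.0581). The 319 against mut-14 smut-1 became 193, 508 and 1750 without its lines 1, 2 and 3 and 29, 50 and 61 without triple mutant lines 1, 2 and 3. With library totals, higher calls went from 49.4% to 61.6% for the triple mutant against the wild type at generation 1 (median 0.07 to 0.29) and from 72.1% to 41.6% against mut-14 smut-1 at generation 50 (median -0.01 to -0.14), and TMM took the generation 1 comparison with mut-14 smut-1 from 52.2% to 36%.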

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

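The tests of the 3 weighed patterns were chosen after the results were seen; the differences between groups and the counts over other splits of the samples were planned before. Apart from the C16C8 genes, each result here drew attention because the effect of prg-1 differed between 2 generations, 2 alleles or 2 genetic backgrounds by a test of the difference itself.

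Core histone small RNAs rose in prg-1 at generation 1, and in tm872 and at generation 50, where the estimated correlation ended the call. Their sum rose by a log2 of 5.02 at generation 1, against reads passed between copies as the whole cause. The lowest generation 50 median over 4 other scalings was 2.65, against scaling. A mutator pathway gain must shrink without mut-14 and smut-1, and did (median -4.10 at generation 1, not called with that correlation), so that pathway may make these small RNAs. The unc-119 allele does not account for it, since neither the triple mutant nor prg-1 carries it. Their histone shares were 0.173 ± 0.0121% and 2.76 ± 0.0524% at generation 1. Core histone mRNA fell in mut-14 smut-1 at generation 1 (median -0.67, adjusted p = 0.422 with the estimated correlation). Histone small RNAs did not rise there. In the triple mutant, without unc-119(ed3), the median was -0.95 but the sum -0.12, so a further cause of lower mRNA stays open.

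Sperm and collagen mRNAs rose in prg-1 at generation 1, though with the estimated correlation the calls of major sperm protein (0.133) and spermatogenesis genes (0.0966) were lost. Library scaling did not account for it, since the lowest median of major sperm protein genes over 3 other scalings was 1.94. A loss of small RNAs against the same genes stays open: it was called for 2.47% of the 162 raised genes, but only 19 had small RNAs tested. Across 14368 genes, the prg-1 and mut-14 smut-1 changes correlated at r = 0.45 and 0.509 with the main axis of the 3 generation 50 wild-type lines (77.6% of variance). With 3 lines a main axis is large, its sign is arbitrary and sperm genes vary among them, so r cannot decide. Developmental timing or sperm number stays open, not told apart from a prg-1 effect on germline genes.

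In the triple mutant, C16C8.16, C16C8.20, C16C8.21 and C16C8.14 were under 1 in all 6 mRNA libraries, chosen for a look after their values were seen. These 4 neighbouring genes stood at 5 or more in each of the other 18 libraries, which is consistent with a deletion carried by this strain, while at generation 1 gldi-6 between them stayed at 146 and C16C8.12 at 160, and C16C8.5 beside them was 99.2 against 216.5 in the wild type. Silencing by a gain of small RNAs has the C16C8.16 small RNA change from the wild type of -4.70 against it. A deletion would need more than 1 piece, or reads of gldi-6 from elsewhere, which the tables do not resolve.

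The other differences are given as values. For mRNA, the prg-1 effect differed between generations for 2248 genes, with medians of 0.20 in core histones, 0.35 in germline proliferation and meiosis genes and -1.03 in neuropeptide and synapse genes. For small RNA it differed between generations for 488 genes. Between tm872 and n4357 it differed for 1583 genes, with medians of -1.38 in core histones, -0.34 in F-box and MATH genes and -0.92 in ERGO-1 class targets. Between the mut-14 smut-1 and wild-type backgrounds, generation 1 mRNA medians differed by 1.29 in core histones, -1.35 in major sperm protein genes, -1.19 in collagens and -2.60 in the silencing readouts, and at generation 50 by 1.19 in core histones and -3.31 in the readouts. Small RNA medians differed by -4.10 in core histones and 2.61 in F-box and MATH genes at generation 1, and by -3.46 in core histones, -4.30 in rRNA genes and 2.15 in F-box and MATH genes at generation 50.

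Other splits of the samples were tried. In each of the 16 comparisons of 3 against 3 libraries the real split was 1 of 10, too few for a share under 0.05. Real counts and the highest of the other splits were 2368 and 1 for polyA selection. Generation 1 mRNA gave 8414 and 1, 11406 and 0, 11158 and 1, and 1684 and 1 for prg-1, mut-14 smut-1, the triple mutant, and the triple mutant against mut-14 smut-1. Generation 50 mRNA gave 1831 and 1, 4538 and 19, 2117 and 0, and 319 and 2. Small RNA gave 4912 and 0 for prg-1 and 5463 and 0 for the triple mutant at generation 1, 5502 and 0 for tm872, and 8627, 8637, 9592 and 5991 against 0 at generation 50. Over 100 splits, the real one included, 2 matched the mRNA difference between generations (highest other 4877). For small RNA 4 did (highest other 1480), and for alleles 5 did (highest other 6165). These splits shuffle prg-1 labels in both tables, so they cannot test whether its effects differ. All other splits with as many calls kept a real pair of groups apart, 1, 3 and 4 of them in turn, which points to the structure of the samples. For core histones called between backgrounds, 1 of 100 splits matched 55 in generation 1 mRNA (highest other 48), 3 matched 4 at generation 50 (highest other 8), and 2 matched 56 in generation 50 small RNA (highest other 56). These splits have the same limit and cannot exclude chance.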

How the results depend on the processing

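Alternatives chosen after seeing the data are named above, and the others were planned. DESeq2 was not run on mRNA, since whole reads were not recovered there, and miRNA scaling was run at generation 50 alone. Of list results, 106 of 106 kept their direction and side of the threshold with median-ratio scaling and with a pseudocount of 5, 104 with TMM and with the block, and 101 with library totals. No filter kept 99, with 4 calls lost and 3 gained, the stricter filter 95, with 8 lost and 2 moved, and DESeq2 37, with 6 lost and 3 gained. Summed core histones kept 13, with 5 lost and 3 gained, and the fit without piRNAs and miRNAs 14, with 2 lost and 3 gained. Where no cause is given below, the cause was not tested.

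With library totals, the count of calls became 190 for the triple mutant against mut-14 smut-1 in generation 50 mRNA, and 1019, 850 and 2669 for the differences of mRNA and small RNA between generations and between alleles. TMM gave 1232 and pseudocount 5 gave 870 for the first 2 of these differences. With miRNA scaling, calls outside piRNAs and miRNAs in the generation 50 triple mutant against mut-14 smut-1 became 889. The stricter filter gave 7148 and 7132 for mut-14 smut-1 and the triple mutant in generation 1 mRNA, 433, 2211, 583 and 552 for the 4 comparisons of generation 50 mRNA, and 5436, 5727, 6271 and 3018 for those of small RNA, where no filter gave 10749 for the last. Without piRNAs and miRNAs those 4 were 4044, 4980, 5039 and 1089. Fits of only the 2 groups, with fewer libraries behind the spread, gave 1019, 1800, 4191 and 13 in generation 50 mRNA and 43 for the triple mutant against mut-14 smut-1 in generation 1 small RNA. They also lost msp-64 in prg-1 (adjusted p = 0.0822), and B0250.8 (0.167), bath-45 (0.187) and oma-1 (0.133) in the triple mutant against mut-14 smut-1, in generation 50 mRNA, and vit-1 (0.0676) and vit-2 (0.0899) in small RNA. The call of his-35 after polyA selection was lost with median ratios (0.0671), TMM (0.0544) and no filter (0.0668).

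The transposon median of generation 50 small RNA in prg-1 reversed with library totals (-0.3193), miRNA scaling (-0.6038), edgeR (-0.387) and TMM (-0.3494), and lost its call without piRNAs and miRNAs (0.07507). The ribosomal protein median of generation 1 mRNA in mut-14 smut-1 reversed with library totals (0.1007). The core histone median of generation 50 mRNA in mut-14 smut-1 reversed without the 2 doubted lines (0.02616). Core histones summed as one feature lost the call in generation 50 mRNA of prg-1 (-0.4691) and in its difference between backgrounds (0.6485); the others are given with their lists. In generation 50 small RNA of mut-14 smut-1 core histones lost it with DESeq2 (-1.428) and without piRNAs and miRNAs (-1.269), gained it with no filter in the generation 1 triple mutant against mut-14 smut-1 (-0.1709), and gained it with pseudocount 0.5 in the difference between generations (-0.3406). Per miRNA count, the log2 share of the csr class at generation 50 became -0.0344, -0.973 and -0.927 in prg-1, mut-14 smut-1 and the triple mutant, that of piRNAs -0.127 in mut-14 smut-1, and that of rRNA -1.35 and -1.24 in mut-14 smut-1 and the triple mutant. Of the total without piRNAs, the csr class was 0.164, 0.0253 and 0.0787, and miRNAs were -0.00204 in the triple mutant against mut-14 smut-1. With calls of 2-fold or more, the log2 odds of higher small RNA and lower mRNA at generation 50 became 2.465 from -1.198.

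Leaving out single libraries gave 1539 to 2288 calls for polyA selection and 1059 to 1704 for the triple mutant against mut-14 smut-1 in generation 1 mRNA. In generation 50 mRNA it gave 435 to 1820, 2432 to 5407, 581 to 1939 and 29 to 1750 for prg-1, mut-14 smut-1, the triple mutant and the triple mutant against mut-14 smut-1. It gave 171 to 681 for the last comparison in generation 1 small RNA and 727 to 4087 for the mRNA difference between generations. Core histone medians ran from -0.634 to 0.03163 in generation 50 mRNA of mut-14 smut-1, from -0.3239 to -0.05445 in generation 1 small RNA of the triple mutant against mut-14 smut-1, and from -0.4585 to 0.05804 in the small RNA difference between generations. The transposon median ran from -0.03735 to 0.1319.

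A replicate block was fitted although the labels give only shared numbers. Same-numbered libraries deviated together by over 0.1 in 1 of 3 pairs in the polyA table, 1 of 18 and 6 of 18 in generation 1 and 50 mRNA, 0 of 15, 0 of 3 and 1 of 18 in small RNA of generation 1, tm872 and generation 50. With the block, calls became 4529 for polyA selection, 146 and 298 for the triple mutant against mut-14 smut-1 in generation 50 mRNA and generation 1 small RNA, and 1244 for the mRNA difference between generations.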

Other observations

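The values here belong to lists fixed beforehand that answered no comparison above, and which comparison to print was chosen after the results were seen. In generation 1 mRNA of mut-14 smut-1, germline lists were lower: germ granule components had 0 higher and 17 lower (0 and 18) of 18, median -0.62, camera adjusted p = 2.26e-06 and 0.217. Nuclear RNAi and heterochromatin factors had 0 higher and 14 lower (0 and 14), median -0.50, camera adjusted p = 8.96e-05 and 0.217. Factors of piRNA biogenesis had 1 higher and 15 lower (1 and 15), median -0.54, camera adjusted p = 0.000528 and 0.217. Early embryo zygotic genes had 2 higher and 13 lower (2 and 13), median -0.72, camera adjusted p = 0.0443 and 0.354. Vitellogenins had 0 higher and 6 lower (0 and 6), median -0.86, camera adjusted p = 0.0327 and 0.448. Argonautes had 4 higher and 14 lower (4 and 14), median -0.43, camera adjusted p = 0.0221 and 0.422, though their mean was 0.04. The early embryo call was lost without mut-14 smut-1 replicate 2 (adjusted p = 0.0805). Body wall muscle genes were higher, with 14 higher and 0 lower (14 and 0), median 0.89, camera adjusted p = 2.26e-06 and 0.217, as were C-type lectins, lysozymes and antimicrobial peptides, with 75 higher and 32 lower (74 and 32), median 0.55, camera adjusted p = 0.00438 and 0.215. Ribosomal protein genes had 3 higher and 31 lower (3 and 5) of 78, median -0.12, camera adjusted p = 0.0327 and 0.737. The stricter filter ended the calls of vitellogenins and Argonautes (adjusted p = 0.27 for each), early embryo genes (0.649) and ribosomal protein genes (0.795). The ribosomal protein call was also lost without wild-type replicate 1 (adjusted p = 0.143) and without mut-14 smut-1 replicates 1 and 2 (0.0622 and 0.123) and with TMM (0.468, median -0.01), and library totals turned the median to 0.10 (0.201). Heat shock genes (9 higher and 4 lower (9 and 4), median 1.24, camera adjusted p = 0.12), intestine genes (6 higher and 5 lower (6 and 5), median 0.08, camera adjusted p = 0.737), male-specific genes (1 higher and 0 lower (0 and 0), median 0.67, camera adjusted p = 0.729) and histone variants (4 higher and 10 lower (4 and 10), median -0.44, camera adjusted p = 0.123) did not pass, and the stricter filter moved the heat shock median to -0.37 and the intestine median to -0.11. Small RNAs of histone variants and linker histones rose in prg-1, with 10 higher and 0 lower (10 and 0) of 13 at generation 1, median 1.09, camera adjusted p = 9.53e-05 and 0.0556, 12 higher and 1 lower (12 and 1) in tm872, median 1.04, camera adjusted p = 0.000144 and 0.221, and 11 higher and 1 lower (11 and 1) at generation 50, median 1.04, camera adjusted p = 3.44e-05 and 0.147.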
